A study of Mus musculus with 9 samples.

How the data were processed

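RNA from 9 samples of the mouse squamous carcinoma line SCCVII was measured on Affymetrix mouse expression arrays, 3 arrays each for the parental culture (PA), lines from tumours grown in stroma without irradiation (NIR) and lines from tumours grown in stroma irradiated beforehand (IR). Per the labels' protocols, RNA was purified with the Qiagen RNeasy Mini Kit, labelled with biotin and hybridized by the standard Affymetrix procedure. The deposited values are RMA expression values on the log2 scale, with RMA named per the submitters' processing notes and no version or settings given. The values ranged from 2.47 to 14.0, and the array medians from 4.44 to 4.52, so no further scaling or logarithm was applied.

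The table held 45100 probe sets, of which 64 were controls, 34944 were annotated to a single gene, 932 to several and 9160 to none. Gene names came from the platform's probe annotation and were updated through Entrez Gene identifiers against a RefSeq table, which matched 34740 of the single-gene probe sets and left 204 unmatched. For each of 18194 genes the probe set with the highest mean over the 9 arrays was tested, which was a choice among several for 9009 genes. Arrays have no counting depth, so their number limits the precision.

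Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per group, no covariates, 2-sided), with 6 residual and 5.48 prior degrees of freedom. All 9 arrays entered a single fit, from which IR minus NIR, IR minus PA, NIR minus PA and the F test over the groups were taken, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Genes distinct in IR were those called in the same direction against both other groups. The genes shared by both comparisons with PA were set beside 100 simulations without group differences. In these all 9 arrays, PA included, were drawn from each gene's mean and spread, independently between genes. On simulated data with the real genes' means and spreads, the procedure called 62 of 67 genes with a true log2 change of 0.5 in IR against NIR, 57 of 67 in IR against PA and 59 of 67 in NIR against PA, and 100% of those with changes of 1 or 2. Of its calls 14 of 209, 14 of 204 and 8 of 200 were false.

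Gene lists were fixed before the data were examined. There were 35 of them, with 809 of 877 members measured, and 34 had the 5 measured members needed for a test. They covered hypoxia targets, CCN and matricellular proteins, integrins, collagens and laminins, matrix proteases, mesenchymal, epithelial and squamous genes, TGF-beta, YAP, Wnt, Notch, p53 and NRF2 targets, immediate early genes, interferon-stimulated genes, the MHC class I pathway, cytokines, angiogenic factors, mitosis, DNA replication and repair, the unfolded protein response, heat shock, glycolysis, the respiratory chain, cholesterol synthesis, ribosomal proteins and markers of tumour-initiating cells. Markers of fibroblasts, macrophages, lymphocytes, endothelium, and muscle, fat and red cells were included because cultures from tumours can hold host cells. The remaining list held the 3 genes that the published study followed. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and members were also adjusted over the list alone.

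The genes named in the text were chosen by a rule fixed before the data were examined. For each comparison these were taken from the 10 largest rises and 10 largest falls among called genes with a single symbol whose groups did not overlap, the study's genes, up to 4 called members of each list that passed, and up to 2 members of every other list, with the 10 genes distinct in IR that differed most from NIR. Members called against the direction of a list, and genes that complete a count of 5 or fewer, were named after their values were seen, as were the single markers of macrophages and fibroblasts given to describe host cells. Immunoglobulin and T cell receptor segments, predicted genes and unnamed transcripts were counted but not named.

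Alternatives planned before the data were examined were a filter on signal, the mean of a gene's probe sets, leaving out probe sets that can bind several transcripts, testing every probe set, median centring, a second quantile normalization, eBayes with trend and robust settings, array weights, a fit of the compared groups alone, the replicate number as a block, a 2-fold minimum, an adjusted p below 0.01, and leaving out each array in turn. For the lists they were camera with an estimated correlation and fry, and for the study's genes each other probe set. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The chromosome and start position of each gene came from the RefSeq table and were used only to order neighbouring genes.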

Results

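Gene expression was measured in 9 samples of SCCVII, a mouse tumour cell line from a squamous cell carcinoma that arose spontaneously in the mouth. The samples formed 3 groups of 3 arrays. PA was the parental line kept in standard culture. NIR was derived from tumours that PA cells had formed in stroma that was not irradiated, and IR from tumours formed in stroma irradiated before the cells were injected. The labels describe the IR tumours as strongly hypoxic and the IR lines as invasive and metastatic even after growth in normoxic culture, whereas the NIR tumours and lines are described as poorly so. The comparison of IR with NIR addressed what set cells from irradiated stroma apart from cells that had also passed through a tumour. The comparisons with PA addressed what separated each derived group from the cells it came from. The samples are called independent, but nothing in the labels says whether the 3 arrays of a group came from separate tumours, lines or dishes, so the p-values may measure only a technical spread between these samples.

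The arrays were alike in overall signal. Their medians ranged from 4.44 to 4.52 on the log2 scale. The 3' minus 5' difference of the Gapdh control probe sets, a sign of RNA integrity, was -0.14 ± 0.021 in IR, -0.10 ± 0.056 in NIR and -0.13 ± 0.038 in PA (SD, n = 3 each). The SD of the log2 differences between a pair of arrays averaged 0.180 within IR, 0.208 within NIR and 0.161 within PA, against 0.233 between IR and NIR arrays, 0.215 between IR and PA and 0.233 between NIR and PA. The closest pair was IR1 and IR2 at 0.129, near the 0.142 of PA1 and PA2, and all 9 arrays were kept as separate samples. IR3 lay further from IR1 and IR2, at 0.203 and 0.209. IR3 also had the highest signal of macrophage markers, with a list mean of 5.06 against 4.62 in IR1, 4.63 in IR2, 4.58 to 4.67 in NIR and 4.41 to 4.53 in PA. The number of arrays limits the precision of every value.

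Among 18194 genes, 426 differed among the groups by limma's F test at a Benjamini-Hochberg adjusted p below 0.05. Without a single array the count was 195 without PA1, 205 without PA2, 244 without IR1, 245 without PA3, 257 without IR2, and 289 to 425 without any of the others.

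Ccn1, which encodes the secreted matricellular protein CYR61, was highest in IR, lowest in NIR and between them in PA. Its probe set (Entrez Gene 16007) read 8.91 ± 0.033 in IR, 7.20 ± 0.15 in NIR and 8.22 ± 0.012 in PA (log2, mean ± SD, n = 3 each). Ccn1 was thus 3.27-fold higher in IR than in NIR (log2 fold change 1.71, SE 0.081, limma adjusted p = 2.56e-06) and 1.61-fold higher than in PA (0.69, adjusted p = 0.00102). It was lower in NIR than in PA (-1.03, limma adjusted p = 7.24e-05). Itgb5 and Itgav encode the subunits of the integrin alpha V beta 5, a receptor for matrix proteins that binds CYR61. Itgb5 (Entrez Gene 16419) read 7.85 ± 0.096 in IR, 7.19 ± 0.40 in NIR and 7.04 ± 0.22 in PA. It rose in IR against PA (log2 fold change 0.81, SE 0.17, limma adjusted p = 0.0483) but did not pass against NIR (0.66, adjusted p = 0.0772). Itgav (Entrez Gene 16410) read 9.38 ± 0.016 in IR, 9.21 ± 0.034 in NIR and 9.12 ± 0.077 in PA. It passed in no comparison, with log2 fold changes of 0.17 against NIR (adjusted p = 0.242) and 0.26 against PA (adjusted p = 0.135). In NIR against PA, Itgb5 changed by 0.15 (adjusted p = 0.788) and Itgav by 0.091 (adjusted p = 0.645).

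Ccn1, Itgb5 and Itgav were followed up in the published study of these samples, so their direction here is not independent evidence. Adjusted over the list alone, all 3 were higher in IR than in NIR and than in PA, and 1 of the 3, Ccn1, was lower in NIR than in PA. The Ccn1 probe set can also bind related transcripts, and the gene's second bright probe set gave 1.58 for IR minus NIR. Dim ones gave 0.38, which passed, and 0.36, which did not, so the mean over all its probe sets is smaller than 1.71. Itgb5 passed between IR and NIR with the mean of its probe sets (0.65, limma adjusted p = 0.0187) and with 2 other probe sets (0.66 and 0.93, adjusted p = 0.0276 and 0.00117). These 2 probe sets can also bind related transcripts, and the remaining one gave 0.34 and did not pass (limma adjusted p = 0.280). Against PA the same 2 passed (0.64 and 0.87, limma adjusted p = 0.0282 and 0.000521) and the remaining one did not (0.40, limma adjusted p = 0.377). The Itgb5 result also turned on single arrays. Without NIR2, whose Itgb5 value was 7.65, the difference between IR and NIR was 0.89 with a limma adjusted p of 0.0115. The call against PA was lost without any of IR1, IR2, IR3, NIR3, PA1, PA2 or PA3, with limma adjusted p up to 0.236 (without PA1).

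**Figure D1:**
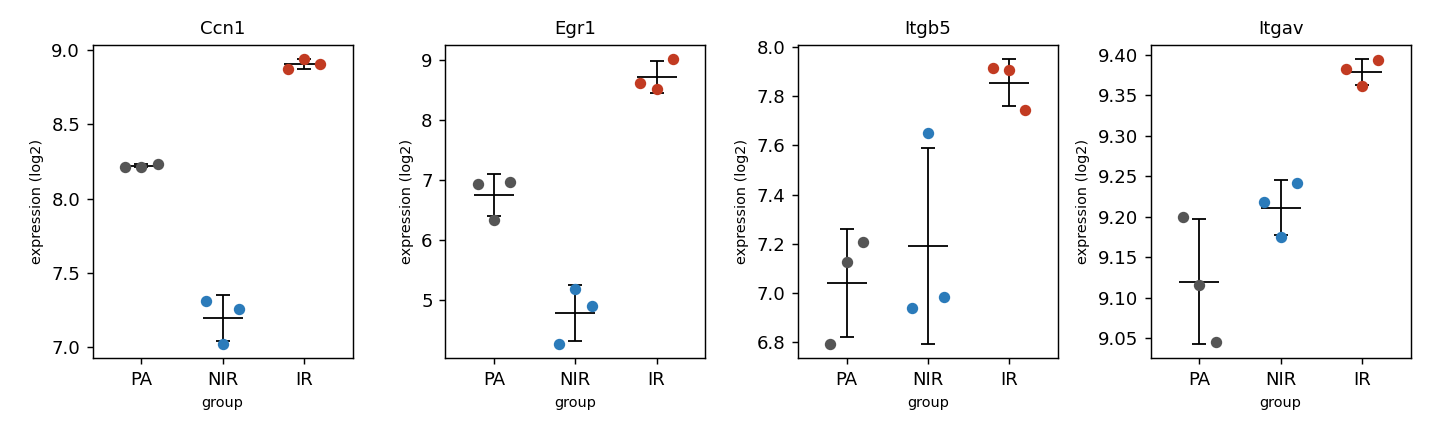
Log2 expression of Ccn1, Egr1, Itgb5 and Itgav on each of the 9 arrays, by group (x axis: PA, NIR, IR); points are arrays, the horizontal bar is the group mean and the whiskers are ± 1 SD, and each y axis has its own range that does not start at 0. Ccn1 and Egr1 have IR above and NIR below PA, and 1 NIR array (NIR2, 7.65) lies close to the IR arrays in Itgb5.

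In IR against NIR, immediate early genes, targets of the hypoxia-inducible factors and TGF-beta response genes were higher in IR, and antioxidant genes and heat shock genes were lower. These camera calls rest on the preset correlation and on 3 to 5 called members of each list in its direction, and none of the 5 held with an estimated correlation (camera adjusted p from 0.0988 to 0.461). With fry the immediate early, TGF-beta and antioxidant lists passed, and the hypoxia and heat shock lists did not (fry adjusted p = 0.0641 and 0.0559). The largest rise was that of Egr1, a zinc finger transcription factor induced by growth factors and stress, which was 15.3-fold higher in IR (Entrez Gene 13653, 8.72 ± 0.27 against 4.78 ± 0.47, SD, n = 3 each, limma log2 fold change 3.94, SE 0.23, adjusted p = 1.27e-05). Its NIR level was close to the median probe set of 4.48, near background, so the exact fold is uncertain. Fstl1, a secreted glycoprotein, rose 3.64-fold, from an NIR level also near background that leaves the exact fold uncertain. Bnip3, a mitophagy protein, rose 3.07-fold. The largest fall was that of Blnk, an adaptor of B cell receptor signalling, by 1.55 on the log2 scale (SE 0.26, limma adjusted p = 0.0181). Gldc, the decarboxylase of the glycine cleavage system, followed with a log2 fold change of -1.17 (SE 0.11, limma adjusted p = 0.00073).

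Limma called 300 genes between IR and NIR, 143 higher and 157 lower in IR, most of them by little: the median size of change was 0.49 on the log2 scale and 16 genes changed at least 2-fold. Other leading rises were Dbp, a circadian transcription factor (log2 fold change 1.62), Ccng2, an unconventional cyclin tied to growth arrest (1.37), and Pdk1, the kinase that shuts off pyruvate dehydrogenase (1.34). Rises of similar rank were those of Enpp3, an ectonucleotidase with a dim signal (1.23), Sertad4 (1.07) and Cp, the copper-carrying ferroxidase ceruloplasmin (1.07). Limma's adjusted p for these rises ran from 0.00233 to 0.0477. Other leading falls included Ramp3, a partner of calcitonin-family receptors (-1.14), Pop1, a subunit of RNase P (-1.04), and Slc15a3, a peptide and histidine transporter with an IR level of 4.13, near background (-0.97). Next came Fam102a (-0.91), Snhg3, a host gene of small nucleolar RNAs (-0.90), Slc14a1, a urea transporter (-0.88) and Cxcl5, a chemokine that attracts neutrophils (-0.82). For these falls limma's adjusted p ran from 0.000701 to 0.0339. Of the 20 genes with the largest changes, not all of them named, 14 passed without any single array. Pdk1 was lost without NIR1 or NIR2 (limma adjusted p up to 0.0544, without NIR1), Cp without any IR array (0.064, without IR3) and Blnk without IR1 or IR2 (0.0685, without IR1). With the mean of a gene's probe sets, Pdk1 and Ccng2 lost their calls too. Ccng2 (0.125, without NIR2) and Cxcl5 (0.0966, without IR1) were lost without any array but IR3, and Slc15a3 (0.0913, without IR2) without any but NIR3 and PA3.

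The 28 targets of the hypoxia-inducible factors shifted upward in IR as a group (camera adjusted p = 2.12e-09, and adjusted p = 0.408 with an estimated correlation). Of these 28, 5 rose, 0 fell and 23 did not pass, or 11 rose adjusted over the list alone, and 26 had a positive log2 fold change. The 5 were Bnip3, Pdk1, Ankrd37 (0.99), Bhlhe40, a transcriptional repressor (0.63), and Ak4, a mitochondrial adenylate kinase. Ankrd37 lost its call without any single array (limma adjusted p up to 0.119, without NIR2). IR3 had the highest hypoxia list mean, at 8.65 against 8.32 in IR1 and 8.29 in IR2, and this was also the array with the highest macrophage markers. The hypoxia shift still passed without IR3 at the preset correlation (camera adjusted p = 6.14e-07). The 20 glycolysis genes shifted upward with no single member called, 4 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0289, and adjusted p = 0.695 with an estimated correlation). That call was lost without IR3 (camera adjusted p = 0.223), NIR1 or NIR3.

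Of 26 immediate early genes, 5 rose, 1 fell and 20 did not pass, or 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 6.04e-06, and adjusted p = 0.279 with an estimated correlation). Beside Egr1, the named rises were Ier2 (log2 fold change 0.80), Fos, a subunit of the AP-1 transcription factor (0.80, with a dim signal), and Dusp6, a phosphatase that inactivates ERK (0.77), while Fosl1, another AP-1 subunit, fell by 0.48. Fosl1 lost its call without any array but NIR1 (limma adjusted p up to 0.118, without IR2). Of 22 TGF-beta response genes, 4 rose and 0 fell, or 6 rose adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.0988 with an estimated correlation). These were Skil (1.02), which encodes a repressor of SMAD signalling, Klf10 (0.80), Id1 (0.63) and Bhlhe40, a member of both this list and the hypoxia list, and another, uncalled probe set of Skil gave -0.079.

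Of 23 antioxidant genes that NRF2 controls, 4 fell, 1 rose and 18 did not pass, or 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.64e-06, and adjusted p = 0.0988 with an estimated correlation). Those that fell were the quinone reductase Nqo1 (log2 fold change -0.77), both subunits of the rate-limiting enzyme of glutathione synthesis, Gclm (-0.49) and Gclc (-0.48), and the drug efflux pump Abcc1 (-0.49). The aldehyde oxidase gene Aox1 rose by 0.57. Nqo1 lost its call without NIR1 (limma adjusted p = 0.0501), and Abcc1 without IR1, IR2, IR3, NIR1 or NIR2 (up to 0.0596, without IR3). Gclm (limma adjusted p up to 0.105, without NIR2) and Gclc (up to 0.111, without IR3) lost theirs without any array. Of 16 cytosolic heat shock genes, 3 fell, Hspa4l (-0.60), Hspa1b (-0.57) and Hspa4 (-0.49), or 6 adjusted over the list alone (camera adjusted p = 0.00151, and adjusted p = 0.461 with an estimated correlation). The heat shock call was lost without NIR1 (camera adjusted p = 0.054). Hspa1b lost its own without any array but NIR2 (limma adjusted p up to 0.0871, without IR2), and Hspa4 without any but NIR3 (up to 0.0937, without NIR2).

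A further 4 lists passed on weaker evidence. Of 35 inflammatory cytokine and chemokine genes, 2 fell in IR, Cxcl5 and the T cell chemokine Ccl5 (-0.69), or 4 adjusted over the list alone (camera adjusted p = 0.00832, and adjusted p = 0.383 with an estimated correlation). Of 20 cholesterol synthesis genes, Tm7sf2, a sterol reductase, rose (0.52), or 4 rose adjusted over the list alone (camera adjusted p = 0.00222, and adjusted p = 0.568 with an estimated correlation). This call was lost without IR1 (camera adjusted p = 0.0623). Of 35 respiratory chain genes, Ndufb3, a subunit of complex I, rose (0.35), as it did adjusted over the list alone (camera adjusted p = 0.0284, and adjusted p = 0.408 with an estimated correlation). The shift was lost without IR1, NIR1 (camera adjusted p = 0.104) or NIR2. Without IR3 the limma adjusted p was 0.13 for Ccl5, 0.123 for Tm7sf2 and 0.103 for Ndufb3, and these calls were also lost without any other array, except NIR2 for Ccl5 and IR2 for Tm7sf2. None of 34 interferon-stimulated genes was called by limma, over all genes or adjusted over the list alone. The list passed, with 26 positive members, as higher in IR (camera adjusted p = 0.0349, and adjusted p = 0.753 with an estimated correlation), and the call was lost without IR1, IR2, NIR1 (camera adjusted p = 0.722) or NIR2.

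The number of genes called between IR and NIR depended on the fit. It was 11, all among the 300, when the PA arrays were left out of the estimate of the spread. It was 77 without IR1, 93 without IR2, 115 without PA1, 119 without NIR1, 128 without IR3, 131 without PA2, 154 without NIR2, 161 without PA3 and 271 without NIR3.

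In IR against PA, interferon-stimulated genes and the MHC class I pathway were lower in IR, and chains of collagen VI, the proteoglycan decorin and a lysozyme gene were higher. The largest fall was that of Ifi27l2a, an interferon-induced gene, which was 9.39-fold lower in IR (7.23 against 10.46, log2 group means; limma log2 fold change -3.23, SE 0.24, adjusted p = 6.36e-05). Irf7, the transcription factor that drives type I interferon genes, was 5.95-fold lower (log2 fold change -2.57, SE 0.13, adjusted p = 2.13e-06). Lyz1, a lysozyme, had the highest fitted rise, 3.55 on the log2 scale (SE 0.46, limma adjusted p = 0.0023), read by a probe set that can also bind related transcripts. Its PA values of 3.17 to 3.33 lay below the median probe set of 4.48, near background, so the size of this rise is uncertain. Lyz1 stood at 8.30 in IR3 against 6.04 in IR1, 5.99 in IR2 and a PA mean of 3.22.

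Limma called 192 genes, 54 higher and 138 lower in IR than in PA, of which 60 changed at least 2-fold. Other leading rises were Egr1 (log2 fold change 1.97), Fstl1 (1.94), the collagen VI chains Col6a3 (1.58) and Col6a1 (1.03), and Enpp3 (1.36, dim). They also included the secreted protein gene Lrrc17 (1.36), Dcn, which encodes decorin (1.24), the calcium-binding protein gene S100a16 (1.03) and Plxdc1 (0.99), with limma adjusted p from 2.13e-06 to 0.0123. Other leading falls were the oligoadenylate synthetase family genes Oasl2 (-2.40) and Oas1a (-1.86), Usp18, which removes the ubiquitin-like modifier ISG15 (-2.40), and Blnk (-2.16). They further included Ifit1, a binder of viral RNA (-1.94), the guanylate-binding protein gene Gbp3 (-1.72), the water channel gene Aqp1 (-1.69) and Zbp1, a sensor of nucleic acids (-1.68), with limma adjusted p from 6.36e-05 to 0.00481. Of these 20 leading genes, 18 passed without any single array, the exceptions being Col6a1, lost without PA1 or PA2 (limma adjusted p up to 0.0867, without PA2), and Plxdc1, lost without PA1 (0.0543).

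Of 34 interferon-stimulated genes, 27 fell in IR, 1 rose and 6 did not pass, or 29 fell and 1 rose adjusted over the list alone. The list median was -1.09 on the log2 scale, and the shift held with an estimated correlation (camera adjusted p = 2.48e-58, and adjusted p = 0.0331 with an estimated correlation). The list mean was 8.16 ± 0.011 in PA and 7.03 ± 0.17 in IR (log2, SD, n = 3 each). The gene that rose was Ifi27 (0.42). Of 14 MHC class I genes, 5 fell and 9 did not pass, or 10 fell adjusted over the list alone (camera adjusted p = 1.99e-13, and adjusted p = 0.00898 with an estimated correlation). The named falls were the peptide transporter gene Tap1 (-0.52), the class I heavy chain genes H2-K1 (-0.49) and H2-D1 (-0.36), and the immunoproteasome subunit gene Psmb9 (-0.38). The probe sets of H2-K1 and H2-D1 can also bind related transcripts. Of these 4, H2-K1 passed without any single array. Tap1 was lost without any IR or PA array (limma adjusted p up to 0.127, without PA2) and Psmb9 without IR1, IR2 or any PA array (0.149, without IR1). H2-D1 was lost without any array but IR3, NIR2 and NIR3 (limma adjusted p up to 0.211, without PA2).

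Of 32 collagen and laminin genes, 2 rose in IR, Col6a3 and Col6a1, and 30 did not pass, or 6 rose adjusted over the list alone (camera adjusted p = 0.000552, and adjusted p = 0.332 with an estimated correlation). Among markers of fibroblasts, the matrix-producing cells of the stroma, 1 of 17 rose, Dcn, of which another, uncalled probe set gave -0.039, or 3 adjusted over the list alone (camera adjusted p = 0.000651, and adjusted p = 0.328 with an estimated correlation). None of 18 macrophage markers was called by limma, 3 rose adjusted over the list alone, and 16 were higher in IR than in PA (camera adjusted p = 2.24e-05, and adjusted p = 0.328 with an estimated correlation). The macrophage list was highest in IR3, where the lysozyme gene Lyz2 read 8.25 against 5.71 in IR1 and 5.78 in IR2, and the list still passed without that array (camera adjusted p = 0.0035). Among the general macrophage markers, Csf1r was 5.53 in IR3 and 5.63 on average in IR1 and IR2.

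Of 29 genes of the unfolded protein response, 2 rose in IR against PA, the stress-induced transcription factor gene Atf3 (0.59) and the protein disulphide isomerase gene Pdia4 (0.49). Adjusted over the list alone, 7 rose and 1 fell (camera adjusted p = 1.97e-07, and adjusted p = 0.328 with an estimated correlation). Of 26 immediate early genes, 3 rose, Egr1, Atf3 and Fos (0.50), or 6 adjusted over the list alone (camera adjusted p = 0.00274, and adjusted p = 0.328 with an estimated correlation). This shift was lost without IR3 (camera adjusted p = 0.216). Atf3 was lost without any IR array, PA1 or PA3 (limma adjusted p up to 0.16, without PA1), Pdia4 without any IR array, PA1 or PA2 (0.13, without PA2) and Fos without IR1, IR3, PA2 or PA3 (0.104, without PA2). Of 23 NRF2-controlled genes, the glutathione transferase gene Gstm2 fell (-1.19), or 2 adjusted over the list alone (camera adjusted p = 2.24e-05, and adjusted p = 0.0621 with an estimated correlation). Of 16 heat shock genes, the small chaperone gene Cryab fell (-0.87), or 3 adjusted over the list alone (camera adjusted p = 3.92e-05, and adjusted p = 0.328 with an estimated correlation). Cryab lost its call without any IR or PA array (limma adjusted p up to 0.135, without PA2).

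Of 20 cholesterol synthesis genes, Tm7sf2 rose in IR against PA (0.74), as it did adjusted over the list alone (camera adjusted p = 0.00453, and adjusted p = 0.549 with an estimated correlation). The shift was lost without IR1 (camera adjusted p = 0.181) or IR2. The 28 hypoxia targets had no called member, with 1 rising adjusted over the list alone (camera adjusted p = 0.00575, and adjusted p = 0.586 with an estimated correlation). Their shift against PA rested on single arrays, being lost without IR3 (camera adjusted p = 0.931) or PA1. The number of genes called between IR and PA was 99 without PA1, 99 without PA2, 109 without IR2, 114 without IR1 and 121 without PA3.

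In NIR against PA, the same interferon and MHC class I lists were lower in NIR, and the matrix genes Mmp2, Lum and Col6a3 were higher. Hypoxia targets and TGF-beta response genes were also lower at the preset correlation, with 3 members called in each list, but not with an estimated correlation (camera adjusted p = 0.571 and adjusted p = 0.345). The largest falls were those of Oasl2, 6.39-fold lower in NIR (6.48 against 9.16, log2 group means; limma log2 fold change -2.68, SE 0.22, adjusted p = 0.000107), and Usp18, 6.28-fold lower (-2.65, SE 0.32, adjusted p = 0.00107). The highest fitted rises were those of Lyz1, whose PA level was near background (log2 fold change 2.30, SE 0.46, limma adjusted p = 0.0362), and Mmp2, a gelatinase that degrades basement membrane collagen (1.61, SE 0.34, adjusted p = 0.047).

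Limma called 236 genes, 69 higher and 167 lower in NIR than in PA, of which 73 changed at least 2-fold. Other leading falls were Ifi27l2a (-2.58), Irf7 (-2.54), Ifit1 (-2.14) and Rtp4, an interferon-induced receptor transporter (-2.01). These were followed by Zbp1 (-1.98), Egr1 (-1.97), Irgm2, an immunity-related GTPase (-1.88), and Xaf1, an interferon-induced gene with a pro-apoptotic product (-1.86), with limma adjusted p from 4.93e-06 to 0.00197. Other leading rises were Acpp, an acid phosphatase (1.59), Lum, which encodes the proteoglycan lumican (1.29), and Col6a3 (1.06). Smaller rises were those of the ubiquitin ligase gene Pdzrn3 (1.04), Ankrd33b (1.02), Lrrc17 (0.96), the corticotropin-releasing hormone receptor gene Crhr1 (0.87) and the focal adhesion gene Tns3 (0.85), with limma adjusted p from 3.86e-05 to 0.0406. Of these 20 leading genes, 15 passed without any single array. Lyz1 was lost without any NIR or PA array (limma adjusted p up to 0.15, without PA3), Acpp without any PA array (0.0804, without PA3) and Lum without NIR1, NIR2 or any PA array (0.119, without PA2). Mmp2 was lost without any array but IR3 and NIR3 (limma adjusted p up to 0.175, without PA1) and Pdzrn3 without any but IR2 and IR3 (0.164, without PA3).

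Of 34 interferon-stimulated genes, 25 fell in NIR, 0 rose and 9 did not pass, or 30 fell and 1 rose adjusted over the list alone. The list median was -1.24 and the list mean in NIR was 6.91 ± 0.25 (camera adjusted p = 1.29e-54, and adjusted p = 0.0391 with an estimated correlation). Of 14 MHC class I genes, 7 fell, or 11 adjusted over the list alone, and all 14 had a negative log2 fold change (camera adjusted p = 3.76e-16, and adjusted p = 0.00532 with an estimated correlation). The named falls were the immunoproteasome subunit genes Psmb9 (-0.64) and Psmb8 (-0.57), Tap1 (-0.57) and Erap1, a peptide-trimming protease (-0.51). Tap1 was lost without PA2 or PA3 (limma adjusted p up to 0.0686, without PA2) and Erap1 without NIR1, PA1 or PA2 (0.0812, without PA1).

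Of 28 hypoxia targets, 3 fell in NIR against PA, Pdk1 (-1.02), Bhlhe40 (-0.56) and Ak4 (-0.53), or 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.23e-05, and adjusted p = 0.571 with an estimated correlation). Bhlhe40 lost its call without PA3 (limma adjusted p = 0.0601), Pdk1 without any array but IR3 and NIR3 (up to 0.178, without PA2) and Ak4 without any but IR1 and IR3 (up to 0.182, without PA3). Of 22 TGF-beta response genes, 3 fell, the inhibitors of DNA binding Id1 (-1.08) and Id3 (-0.68) and Bhlhe40, or 5 adjusted over the list alone (camera adjusted p = 0.00809, and adjusted p = 0.345 with an estimated correlation). The shift was lost without NIR1 (camera adjusted p = 0.074). Id3 lost its call without NIR1, NIR2 or any PA array (limma adjusted p up to 0.143, without PA2). Of 26 immediate early genes, Egr1 fell and Fosl1 rose (0.51), or 7 fell and 2 rose adjusted over the list alone, with the list lower in NIR (camera adjusted p = 0.00809, and adjusted p = 0.474 with an estimated correlation). Fosl1 lost its call without any of IR1, IR2, PA1, PA2 and PA3 (limma adjusted p up to 0.151, without PA3).

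A further 4 lists passed in NIR against PA, each losing its call without any of 4 single arrays. Among 17 fibroblast markers, 2 rose, Lum and Dcn (0.81), or 4 adjusted over the list alone (camera adjusted p = 0.0427, and adjusted p = 0.589 with an estimated correlation; 0.194 without NIR2, and lost also without NIR1, PA1 or PA2). Of 29 genes of the unfolded protein response, the transcription factor gene Ddit3 rose (0.59), as it did adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.644 with an estimated correlation; 0.171 without NIR3, and lost also without NIR2, PA1 or PA3). No respiratory chain gene of 35 was called, and 1 fell adjusted over the list alone, with the list lower in NIR (camera adjusted p = 0.0211, and adjusted p = 0.398 with an estimated correlation; 0.113 without NIR1, and lost also without NIR2, PA1 or PA2). No cytokine or chemokine gene of 35 was called, and 1 rose adjusted over the list alone, with the list higher in NIR (camera adjusted p = 0.0427, and adjusted p = 0.474 with an estimated correlation; 0.14 without PA2, and lost also without NIR1, NIR2 or PA1). Dcn lost its own call without any array but IR3 and NIR3 (limma adjusted p up to 0.178, without PA2), and Ddit3 without any NIR or PA array (0.122, without PA1).

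Macrophage markers did not pass as a list in NIR against PA (camera adjusted p = 0.0526), and 13 of 18 were higher than in PA. Among them the mannose receptor gene Mrc1 rose (0.75), a call lost without NIR1, PA1 or PA3 (limma adjusted p up to 0.099, without PA1). The NRF2-controlled genes did not pass as a list either (camera adjusted p = 0.18), with Gstm2 (-0.95) and Aox1 (-0.47) lower in NIR. Aox1 lost its call without any array but IR3 and NIR2 (limma adjusted p up to 0.192, without PA2). The heat shock genes did not pass (camera adjusted p = 0.784), and of these Cryab fell (-1.02) while the list median was 0.063. The number of genes called between NIR and PA was 121 without PA3, 124 without PA1, 129 without PA2 and 370 without IR3, which is not part of this comparison but enters the estimate of the spread.

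**Figure D2:**
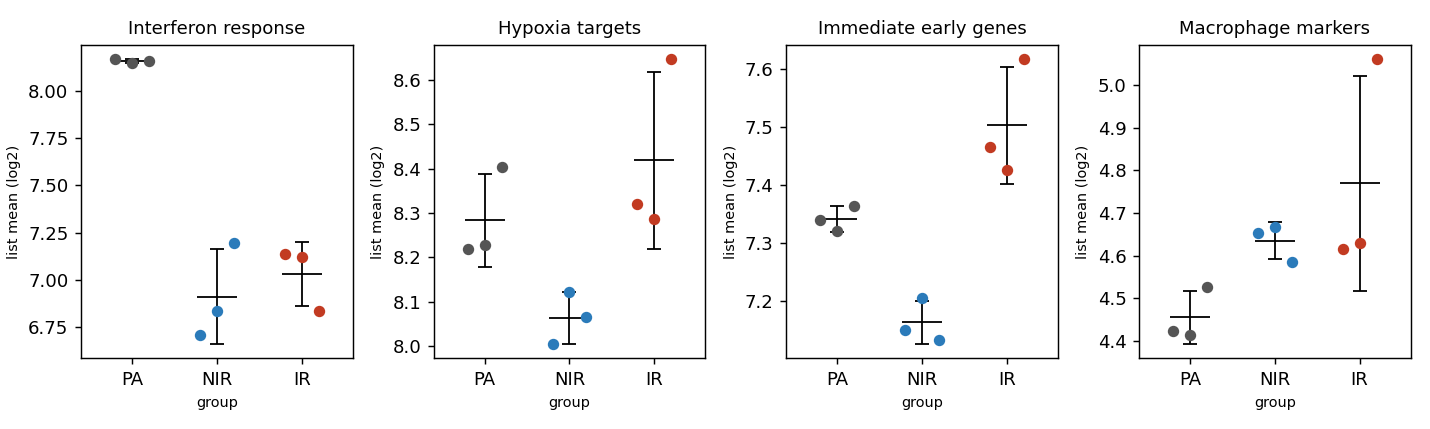
Mean log2 expression of the measured members of 4 gene lists (interferon response, hypoxia targets, immediate early genes and macrophage markers) on each array, by group (x axis: PA, NIR, IR); points are arrays, the horizontal bar is the group mean and the whiskers are ± 1 SD, and each y axis has its own range that does not start at 0. The interferon list is at 8.16 in PA and at 7.03 or below in the means of both derived groups, and IR3 is the highest array for the other 3 lists.

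Most genes called in both derived groups against PA moved the same way. There were 103 such genes, 14 higher and 89 lower than in PA, and the shared falls included Irf7, Oasl2, Usp18, Ifit1, Ifi27l2a and Zbp1, and the shared rises Lyz1, Col6a3, Lrrc17 and Dcn. Only Ccn1 and Egr1 were called in opposite directions, higher than PA in IR and lower in NIR. Independent lists of these sizes would share 0.205 genes higher and 1.27 lower. Because both comparisons use the same PA arrays, 100 simulations of unchanged groups sharing simulated PA arrays were run. They gave 0.01 shared calls on average, but data without differences yield almost no calls, so this value says nothing on shared controls. The simulations gave 32.9 shared genes, at most 43, when lists as long as the observed ones were taken from the top. Over all genes the log2 fold changes of the 2 comparisons had a correlation of 0.492, against 0.501 in the simulations, and a covariance of 0.0144 against 0.00482, a difference of 0.00957. Genes are not independent replicates. With 3 PA arrays the controls could not be split into separate pairs, so part of the excess may come from the shared controls. The count of shared genes was 64 without PA1, 65 without PA2 and 68 without IR2.

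**Figure D3:**
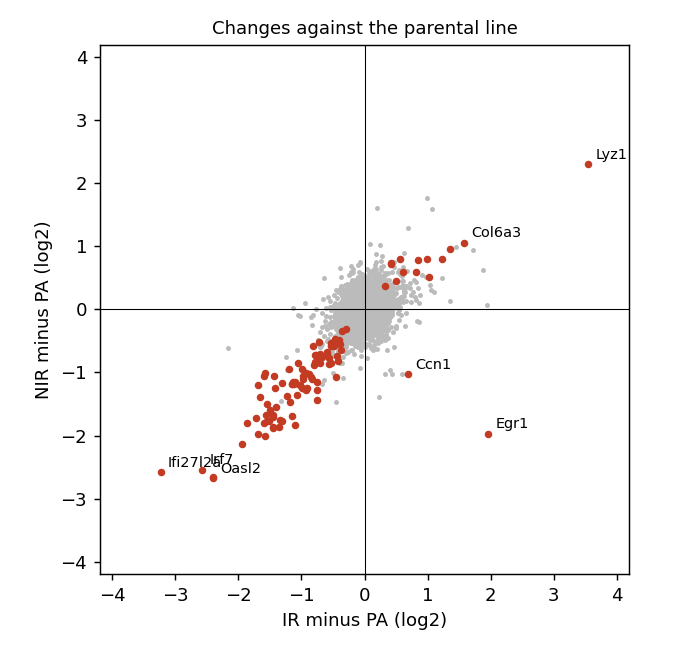
Log2 fold change of IR minus PA (x axis) against NIR minus PA (y axis) for all 18194 genes in grey, with genes called in both comparisons in red. The labelled interferon-stimulated genes lie at the lower left, Lyz1 and Col6a3 at the upper right, and Ccn1 and Egr1 at the lower right, with IR above and NIR below PA.

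IR was set apart from both other groups by 39 genes, 20 higher and 19 lower. The rises with the largest difference from NIR were those of Egr1, Fstl1, Ccn1, Enpp3, Sertad4 and Skil, and the falls included those of Blnk, Gldc and Slc15a3. The call of Skil against PA was lost with the mean of its probe sets. Fstl1 read 6.77 ± 0.56 in IR, 4.91 ± 0.23 in NIR and 4.83 ± 0.15 in PA, and Gldc read 5.17 in IR, 6.34 in NIR and 6.31 in PA. Independent lists would share 0.424 genes higher and 1.19 lower, and simulated lists of equal length that share the IR arrays had 37.7 genes in common, so the length of the overlap was close to that of such lists. The count was 13 without IR1, 16 without PA1 or PA2, 18 without IR2 or PA3, and 8 when each comparison was fitted on its own groups alone.

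The lists that did not pass in IR against NIR covered the matrix, cell identity, growth and other cell types, and some of them, such as the collagens, passed against PA. In IR against NIR, Ccn1 was the only called member of 19 CCN and matricellular genes (camera adjusted p = 0.195), and Ccn1 and Fstl1 were the only called ones of 20 YAP targets (camera adjusted p = 0.195). None of 19 integrin genes (camera adjusted p = 0.284) or 35 matrix protease genes (camera adjusted p = 0.729) was called between IR and NIR, and Mmp2 had a log2 fold change of -1.42 (limma adjusted p = 0.0669). Of the collagens and laminins, Col6a3 rose in IR against NIR (0.52; camera adjusted p of the list = 0.255). The simple keratin gene Krt18 rose (0.57) among 28 squamous and keratin genes (camera adjusted p = 0.58). Fosl1 was the only called one of 20 mesenchymal genes (camera adjusted p = 0.437), and none of 26 epithelial genes was called (camera adjusted p = 0.934). Of the 26 epithelial genes 14 lay below the median probe set in mean signal. The same held for 16 of 28 squamous and keratin genes and 13 of 19 CCN and matricellular genes, which limits these results. Krt18 was lost without any IR array (limma adjusted p up to 0.0609, without IR1) and Col6a3 without any array but NIR2 (0.112, without IR2).

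For growth and genome maintenance, the spindle checkpoint kinase gene Bub1 rose (0.40) among 31 mitotic genes (camera adjusted p = 0.775), and the p53 targets Aen (-0.62) and Zmat3 (-0.34) fell among 25 (camera adjusted p = 0.372). None of 33 DNA replication genes (camera adjusted p = 0.843) or 29 DNA repair genes (camera adjusted p = 0.934) was called between IR and NIR. The phosphatase subunit gene Ppp1r15a rose (0.59) among 29 genes of the unfolded protein response (camera adjusted p = 0.0988), and H2-M3 rose (0.43) among the MHC class I genes (camera adjusted p = 0.173). The growth factor gene Ereg fell (-0.49) among 28 angiogenic and growth factor genes (camera adjusted p = 0.934). Bub1 was lost without any IR array (limma adjusted p up to 0.0591, without IR1), Ereg without IR1, IR2, IR3, NIR1 or NIR2 (0.0755, without IR1) and H2-M3 without any array but PA3 (0.0709, without IR3). Aen (limma adjusted p up to 0.126, without NIR1) and Zmat3 (0.144, without IR3) were lost without any array but NIR3, and Ppp1r15a without any array (0.118, without NIR1). No member was called among 20 Wnt targets (camera adjusted p = 0.282), 18 Notch genes (camera adjusted p = 0.934), 15 markers of tumour-initiating cells (camera adjusted p = 0.934) or 28 ribosomal protein genes (camera adjusted p = 0.934). Of the 15 markers of tumour-initiating cells 8 lay below the median probe set in mean signal.

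Of the markers of other cell types, none was called between IR and NIR among 18 for macrophages (camera adjusted p = 0.195), 17 for fibroblasts (camera adjusted p = 0.596) and 13 for lymphocytes (camera adjusted p = 0.976). The same held for 17 markers of endothelium (camera adjusted p = 0.336) and 13 for muscle, fat and red cells (camera adjusted p = 0.934). Many of these markers were dim, which limits these results. Below the median probe set in mean signal lay 9 of 18 for macrophages, 9 of 13 for lymphocytes, 9 of 17 for endothelium and 9 of 13 for muscle, fat and red cells. Against PA, the lists without a call reached camera adjusted p from 0.0592 to 0.963 in IR and from 0.0526 to 0.958 in NIR. Their called members in IR against PA were Adam8 (0.52), Snai2, a driver of epithelial-mesenchymal transition (0.63), Krt18 (0.55), Skil (0.84), Id1 (-0.45), Ereg (-0.41), Fstl1, Ccn1 and Itgb5. In NIR against PA they were Col6a3, Mmp2, Fosl1, Ccn1, Tead1, the DNA-binding partner of YAP (0.45), Trp53inp1 (-0.65), Fzd7, a Wnt receptor (-0.53), Gstm2, Aox1, Cryab and Mrc1. In IR, Adam8 lost its call without IR2, NIR3 or any PA array (limma adjusted p up to 0.17, without PA2) and Krt18 without IR1, IR2 or any PA array (0.0901, without PA2). Skil lost its call with the mean of its probe sets. Snai2 lost its call without any array but NIR1 and NIR3 (limma adjusted p up to 0.185, without PA3), Id1 without any but IR3 (0.221, without PA2) and Ereg without any but NIR2 and NIR3 (0.239, without PA2). In NIR, Tead1 lost its call without PA2 (limma adjusted p = 0.058), Fzd7 without PA2 or PA3 (0.0864, without PA2) and Trp53inp1 without any array but IR2 and IR3 (0.14, without PA2). List median, mean and camera direction differed in sign for 6 lists in IR against NIR, 4 in IR against PA and 7 in NIR against PA, none of which passed.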

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

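In this part, the tests of array scaling, of macrophages and lymphocytes as a source of the interferon signal and of macrophages carried over from the tumours were chosen only after the result was seen.

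Ccn1 and Egr1 stood out because IR and NIR moved apart from PA in opposite directions. IR minus NIR, which is the sum of these changes and no separate evidence, was 1.71 for Ccn1 and 3.94 for Egr1 on the log2 scale. Probe sets without a single gene name, which the comparisons by gene do not use, also held differences when every probe set was tested with limma. Of 10092 such probe sets, 34 were called between IR and NIR (13 higher, 21 lower), 39 between IR and PA (7 higher, 32 lower) and 55 between NIR and PA (15 higher, 40 lower).

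Interferon-stimulated genes were lower in both derived groups than in PA. The array medians ranged only from 4.44 to 4.52, so a remaining difference between them is too small to account for this. The list median stayed at -1.07 or lower under median centring and a second quantile normalization. Arrays already so alike could hardly have given another outcome, so this check adds no evidence. The macrophage markers showed no excess in the PA cultures. Of 18 markers, 16 were higher in IR and 13 in NIR than in PA. All 6 derived arrays exceeded every PA array in the list mean without Lyz2. However, 9 of the 18 markers lay below the median probe set in mean signal. Expression of such markers by the derived tumour cells was not excluded either, so macrophages in the PA cultures stay open. Lymphocytes stay open as well, since the list medians of IR and NIR minus PA were near 0 over mostly dim markers. The smaller of these medians was 0.035. An interferon-inducing event shared by the PA cultures, such as an infection, also stays open, because the gap of 0.95 between the lowest PA and the highest derived list mean coincides with the groups and cannot be told apart from them. Passage through a tumour, which the design names, may equally account for it and was not tested separately.

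Hypoxia targets and immediate early genes with Ccn1 were higher in IR than in NIR at the preset correlation, with 5 of 28 and 5 of 26 members called higher, but neither list held with an estimated correlation (camera adjusted p = 0.408 and 0.279). Differences between single dishes in oxygen, density, serum or harvest stay open for both lists, because the labels do not say that the arrays of a group came from separate dishes, so the ratios of 0.98 and 1.77 between the difference of the list means and the largest range within a group decide nothing. Without IR3, 0.68 of the difference was left for the hypoxia targets and 0.83 for the immediate early genes. Both lists still passed without it at the preset correlation (camera adjusted p = 6.14e-07 and 0.000276). The hypoxia list means of IR1 and IR2, 8.32 and 8.29, lay above those of NIR, at most 8.12. This argues against IR3 as the whole cause for either list, while a part from IR3 stays open. Handling shared by all samples of a group, such as the time of harvest or feeding, also stays open because the labels give no dates. The origin of the cells in irradiated stroma stays open beside it.

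Macrophage markers were higher in IR than in PA, most of all in IR3, and fibroblast markers in both derived groups, while macrophage markers did not pass in NIR (camera adjusted p = 0.0526), and none of these calls held with an estimated correlation (adjusted p = 0.328 for both lists in IR and 0.589 for fibroblasts in NIR). Macrophages carried over from the tumours may account for the macrophage markers, but this was not decided. That 16 of 18 list members were higher in IR than in PA restates the pattern, and expression by the tumour cells would give the same count. IR3, highest in Lyz2 at 8.25, was also highest in Cd68 (5.83), Tyrobp (5.39), Mpeg1 (5.26) and Cd53 (4.81). Csf1r was not higher in IR3 than in the mean of IR1 and IR2 (difference -0.091), but it read 5.59 in PA already. By the same measure the difference was -0.044 for Adgre1 and 0.16 for Ptprc. Adgre1 (3.87) and Ptprc (3.88) were not higher in IR3 than in IR2 (4.05 and 3.88). Both were below the median probe set on every array, as Cd53 was on every array but IR3. The markers therefore do not decide between carried-over macrophages and expression by the tumour cells. Fibroblasts cannot be judged by their abundant transcripts, because the parental cells themselves had these, with Col1a1, the lowest of 3 collagen genes tested, at 6.25, Col1a2 at 11.28 and Col3a1 at 11.25 in PA. The marker Dpt, not called in either group against PA, averaged 5.05 in PA and 6.81 in NIR. It read 7.30 in IR3 but 5.42 on average in IR1 and IR2. A single uncalled marker does not decide whether fibroblasts were carried over. Expression of the fibroblast genes by the tumour cells after passage through a tumour stays open.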

How the results depend on the processing

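None of the alternatives here was chosen only after the result was seen. The 121 results for named genes were refitted with median centring, trend and robust settings, the mean of probe sets, the replicate block and each array left out, but not with the other settings. Under these 62 kept their call throughout, 58 lost it without at least 1 array and 0 reversed. Skil in IR against PA lost its call only with the mean of probe sets. Among the settings left out was the fit of the compared groups alone, which kept 11 of the 300 calls in IR against NIR. Of 30 calls for gene lists, 17 held without any single array, 4 held with an estimated correlation, and the same 4, interferon-stimulated and MHC class I genes against PA, held throughout. Signal near background limits what can be read for dim genes such as Fos and Enpp3, and for genes dim in a single group such as Lyz1, Egr1 and Slc15a3. Where a value below differs from the report, the cause was not tested, except that a stricter threshold or a 2-fold minimum lowers a count by construction.

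Without a single array, the genes called ranged from 77 to 271 in IR against NIR (77 without IR1, 93 without IR2), from 99 to 214 in IR against PA, from 121 to 370 in NIR against PA (370 without IR3, including all 236), and from 195 to 425 in the F test. Genes distinct in IR ranged from 13 to 36 and shared genes from 64 to 112. Lists passing ranged from 6 to 11 in IR against NIR (6 without NIR1) and from 5 to 11 in NIR against PA (5 without PA1). For Itgb5 the log2 fold change ranged from 0.54 to 0.89 in IR against NIR, called without NIR2, from 0.69 to 0.90 in IR against PA, lost without 7 arrays and up to an adjusted p of 0.236 without PA1, and from -0.080 without NIR2, a change of sign, to 0.27 in NIR against PA.

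With array weights, 467 genes were called in IR against PA, 382 in NIR against PA and 761 by the F test, 91 were distinct in IR and 166 were shared. With every probe set tested 161 were shared. With only the groups compared, 11 genes were called in IR against NIR and 8 were distinct in IR. With a 2-fold minimum the counts were 16, 60 and 73 for IR against NIR, IR against PA and NIR against PA, 95 for the F test, 5 distinct in IR and 44 shared, and with an adjusted p below 0.01 they were 41, 100, 108, 158, 12 and 64. The remaining settings gave 228 to 390 genes in IR against NIR.

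An estimated correlation left 0, 2 and 2 lists in the same order, and fry 7, 3 and 4. In IR against NIR fry passed the TGF-beta, immediate early, NRF2, cytokine, respiratory chain, CCN and Wnt lists (fry adjusted p from 0.00306 to 0.0399). The hypoxia, heat shock, cholesterol, glycolysis and interferon lists did not pass there. Against PA fry passed the interferon and MHC class I lists in both groups, with NRF2 targets in IR, and TGF-beta and Wnt targets in NIR. Other probe sets of Ccn1 gave 0.36 in IR against NIR, 0.13 and 0.25 in IR against PA, and -0.25 and -0.11 in NIR against PA, none of them called. Other probe sets of Itgav gave -0.025 and -0.078 in IR against NIR, -0.011 in IR against PA, and -0.095 and -0.031 in NIR against PA. Itgb5 was called in IR against NIR with the mean of its probe sets (0.65, adjusted p = 0.0187) and with other probe sets (0.66, adjusted p = 0.0276; 0.93, adjusted p = 0.00117), 1 other probe set was not called in IR against PA (0.40, adjusted p = 0.377), and others gave -0.017 and -0.054 in NIR against PA.

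The replicate numbers do not pair the samples, since 0 of 9 pairs of same-numbered arrays had a correlation of deviations over 0.1 (-0.201 to 0.0974) and 1 of 9 arrays correlated best with its own number. With the replicate number as a block, 230, 164 and 203 genes were called in the same order, 330 by the F test, 28 distinct in IR and 88 shared, and 10, 11 and 12 lists passed.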

Other observations

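Apart from the count of genes distinct in NIR and the medians of the gene windows against PA, none of the tests in this part was chosen only after the result was seen.

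NIR, too, was set apart from both other groups, by 60 genes, 25 higher and 35 lower. Simulated lists of equal length that share the NIR arrays had 43.0 in common (SD 5.59, at most 66), so 60 lay within their range. The genes lower in NIR included Ccn1, Egr1 and Id1, an inhibitor of DNA binding by differentiation factors, whose calls held without any single array in both comparisons. This count was not refitted without single arrays.

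Neighbouring genes that move together in 1 group would be a sign of a gained or lost chromosome segment. The largest median over 25 neighbouring genes, among 11331 windows over 11811 genes, was tested against 1000 permutations of the gene order for 4 profiles. In IR against NIR it was 0.20 on the log2 scale, from Hacd4 to Pgm1, with 22 of 25 genes higher in IR (permutation p = 0.013, Benjamini-Hochberg 0.026), and in IR against PA it was 0.14, from Sgk1 to Tspyl1, with 24 of 25 higher (p = 0.011, Benjamini-Hochberg 0.026). The first window had medians of 0.052 for IR minus PA and -0.048 for NIR minus PA, so its difference was spread over both groups, and a segment changed in a single group stays open there. The second had -0.043 for NIR minus PA, and for it a gained segment in some IR cells may account for the shift, as a hypothesis, although medians this small could also come from neighbours that are regulated together. In NIR against PA the largest median was 0.15 (permutation p = 0.0999, Benjamini-Hochberg 0.133), and in IR3 against IR1 and IR2 it was 0.20 (p = 0.165, Benjamini-Hochberg 0.165), neither of which passed.

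Other splits of the arrays were refitted with limma. Among 100 splits of the 9 arrays into 3 groups of 3, the real 1 included and the others drawn at random, 1 gave as many as 426 genes by the F test, and the highest other count was 100. That highest other split kept the PA arrays together and mixed IR with NIR. The result argues against chance for the grouping of all 9 arrays, but 100 splits cannot exclude it. Nothing follows from it for differences between single cultures if arrays of a group share a culture. For each pair of groups there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 300 genes and the highest other 3 in IR against NIR, 192 and 0 in IR against PA, and 236 and 0 in NIR against PA.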
